A study of Mus musculus with 182 samples.

How the data were processed

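RNA of whole mouse kidneys and of livers was sequenced in 5 runs, and the authors deposited a table of counts per gene for each run, as whole numbers that differ in their column sums and were not normalized. Per the submitters' processing notes, STAR 2.7.9a, featureCounts 2.0.1 and genome build GRCm39 were used; the notes list the tools without their order. The tables of the single-end SMARTer, DNBseq and paired-end SMARTer runs carry the columns that featureCounts writes, with 53599 genes each. The tables of both poly-A runs carry Ensembl genes, 40481 after repeated entries that held the same counts were dropped, and their counting tool is not given in the sources used here. Replicates were not pooled, but the labels do not always say that libraries come from separate animals, and p values then measure only the spread between libraries, which can be technical. In the paired-end SMARTer run 60.6 to 79.2% of counts above 20 were even numbers, against 48.9 to 53.1% in the other runs, an excess as from counting both mates of a pair, so its depth is taken as overstated. A count of 0 allows up to 3 counts of the library, and such floors cover counting error only, since the labels name no molecular identifiers.

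Libraries were grouped by the labels into 46 groups by tissue, sex, age, strain, surgery, treatment and genotype. The labels call the mice of 79 weeks C57BL/6NCrl, while the series text names C57BL/6J for that age. In all 30 comparisons were made, each within a run except for a pair of liver comparisons across runs. Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 (estimateDisp, robust glmQLFit, glmQLFTest; two-sided) in R 4.3.3 after TMM scaling and filterByExpr. P values were adjusted by Benjamini and Hochberg over the genes of a comparison, and genes at an adjusted p under 0.05 were called; standard errors are the log2 fold change divided by the square root of F. The groups of 79 weeks, those of the hormone experiment of the paired-end run, the kidneys of the kidney and liver run and, for comparisons across runs, the livers were each fitted together, and other comparisons used their own groups. Interactions were contrasts in these fits, and sex was a term of the fits of the smaller testosterone experiment and of the Esr1 deletion label in the paired-end run. Levels are means of TMM-scaled CPM with the SD over libraries. Gene lists were tested with camera of limma 3.58.1 (two-sided) on log2 CPM with a prior count of 2, with a preset correlation of 0.01 and with an estimated one, adjusted over the lists of a comparison. Members were also adjusted over the list alone.

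The comparisons, tests, lists, naming rule and alternatives were fixed before the data were examined, apart from overlaps of calls and what is said to be chosen later. The 29 kidney lists, from background knowledge, were male-biased and female-biased kidney genes, organic anion and cation transporters, amino acid and glucose transporters, cytochrome P450 genes, peroxisome and fatty acid oxidation, cholesterol synthesis, polyamine metabolism, cell cycle, nephron progenitor and developing nephron, tubule injury, immediate early and heat shock genes, circadian clock genes, nuclear receptors and cofactors, Y-linked genes and X-linked genes escaping inactivation, and markers of immune cells, proximal tubule S1 and S2, proximal tubule S3, podocytes, thick ascending limb and distal tubule, collecting duct, endothelium, stroma and matrix, fat, adrenal cortex, skeletal muscle, exocrine pancreas and erythroid cells. The 18 liver lists took up 10 of these and added male-biased and female-biased liver genes, the growth hormone and STAT5 pathway, bile acid metabolism, lipogenesis, acute phase proteins, gluconeogenesis and amino acid catabolism, and liver non-parenchymal markers. Genes were named by a rule: the targeted genes, a fixed panel of sex-biased genes, up to 5 rises and 5 falls per comparison, and up to 4 members of each list with the smallest adjusted p. The rises and falls were the largest among called genes with at least 10 CPM in the higher group and no overlap between libraries, without unnamed, Y-linked or Xist genes. For groups at 0 or near 0 counts levels are given in place of a fold. The set of genes that differed by at least 2-fold at 8 weeks, without Y-linked genes and Xist, was tested with camera in kidney comparisons of other libraries, adjusted over these comparisons and both sets.

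Alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, age as a covariate, a block for the replicate number, a single fit of the 12 intact groups of the single-end run, each library left out in turn, and, chosen after the data were seen, no mitochondrial and ribosomal RNA genes, halved counts for the paired-end run, and the doubted libraries left out. A count was taken as changed beyond 1.5 times the reported one. Other splits of the libraries of each comparison, at most 100, were fitted in the same way. A library was set apart when Dixon's ratio of its gap to the range of its group (4 to 10 libraries) passed the 95% value. Strain markers were genes that differed at least 4-fold and without overlap between C57BL/6J (0 to 8 weeks) and gonadectomized C57BL/6NCrl libraries of the single-end run, with at least 5 CPM and a prior of 0.5 CPM. The fits were tested on simulated counts with 200 changed genes of at least 5 CPM: at the sizes of 5 comparisons, 90.0 to 95.0% of the 2-fold and 97.0 to 100.0% of the 4-fold changes were called, and 3.0 to 7.2% of calls were false. Tables were read with data.table, version 1.17.8, and figures drawn with matplotlib 3.10.9 in Python 3.11.15. The gonadectomized mice without injection and the males with loss of Ar of the paired-end run entered no comparison, for lack of matched controls.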

Results

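Gene counts from RNA sequencing were available for 182 mouse libraries in 46 groups, 163 of whole kidney and 19 of liver, from 5 sequencing runs. A single-end SMARTer run (SMARTer is a kit for copying RNA into libraries) held 67 kidney libraries of 17.2 to 30.7 M counts, M standing for mega. It covered both sexes from birth to 79 weeks and a small hormone experiment. A DNBseq run held 25 kidney libraries of 70.6 to 78.6 M counts, of males with loss of Ar in the nephron and of both sexes labelled with deletion of Esr1 there, with controls. A paired-end SMARTer run held 47 kidney libraries of 24.8 to 86.9 M counts, of intact, gonadectomized and testosterone-treated mice, of females with loss of Ar, and of a smaller set labelled with deletion of Esr1. A liver poly-A run held 10 libraries of 40.2 to 55.3 M counts, of males with loss of Ar in hepatocytes and of controls. A kidney and liver poly-A run held 33 libraries of 40.4 to 68.7 M counts, of mice without Ar in any tissue and of mice labelled with deletion of Tbx10 or Neurog2 in the nephron. Ar encodes the androgen receptor, Esr1 the estrogen receptor alpha, and Tbx10 and Neurog2 transcription factors. On GRCm39, Ar (ENSMUSG00000046532) lies on chromosome X, 97192375 to 97366821, plus strand, and Esr1 (ENSMUSG00000019768) on chromosome 10, 4561593 to 4955614, plus strand. Tbx10 (ENSMUSG00000037477) lies on chromosome 19, 4042752 to 4049512, plus strand, and Neurog2 (ENSMUSG00000027967) on chromosome 3, 127426784 to 127429280, plus strand. Cre under Six2 regulatory sequence acts in nephron progenitors and so in the nephron, Sox2-Cre acts throughout the embryo, and Alb-Cre acts in hepatocytes. The comparisons ask which genes differ between the sexes, from what age, and which depend on the gonads, on testosterone or on these genes.

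A value in parentheses after a gene is its log2 fold change ± standard error. A pair of values joined by "against" gives the mean CPM (counts per 1 M counts, TMM-scaled) of the first and then the second group, and n counts libraries. Genes are said to rise or fall only at an adjusted p under 0.05 in the edgeR fit. Genes named for the size of their change showed no overlap between the libraries of the compared groups. For a gene list, adjusted p is that of camera with a preset correlation, and the value after "then" that with an estimated one, and counts within the list are adjusted over it alone.

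The first question was when the kidneys of C57BL/6J males and females come to differ. At birth (n = 4 per sex) edgeR called no gene, with 2514 genes at an unadjusted p under 0.05, and DESeq2 called 1, Xist, the X-inactivation RNA of female cells. In a single fit of all 12 intact groups, which span the ages, 1991 genes were called at birth. The library labelled female 3a held Xist at 0.1 CPM (196 to 218 in the other females) and Y-linked genes at 262 CPM (0.625 to 1.51 in the others). Without it 5 genes were called, Xist and the Y-linked Kdm5d, Eif2s3y, Uty and Ddx3y. At 2 weeks (n = 5 per sex) the 6 calls were sex-chromosome genes, among them Ddx3y (9.55 ± 0.27), Kdm5d (8.39 ± 0.42), Uty (8.28 ± 0.30) and Xist (-8.54 ± 0.24). No gene of the fixed kidney panel of sex-biased genes was called at 2 weeks, and DESeq2 called 14 genes in all.

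At 4 weeks (n = 5 per sex) 494 genes differed, 330 higher and 164 lower in males. Of these 125 and 76 differed by at least 2-fold. Male kidneys held more RNA of the cytochrome P450 enzymes Cyp2j13 (6.82 ± 0.46, 64.2 against 0.56) and Cyp4b1 (3.31 ± 0.37) and Cyp2e1 (2.24 ± 0.18). They also held more of the medium-chain acyl-CoA synthetase Acsm3 (5.47 ± 0.64), the organic anion transporter Slco1a1 (4.42 ± 0.82) and the amino acid transporter Slc7a13 (4.07 ± 0.23, 932 against 55.7). Tbx10 (2.59 ± 0.19, 17.8 against 2.96) was among the male-biased genes at this age. The UDP-glucuronosyltransferase Ugt1a2 (-4.18 ± 0.54, 25.5 against 462) was lower in males, as were the transporters Slc22a27 (-2.25 ± 0.42), Slc17a2 (-2.18 ± 0.25) and Slc7a12 (-1.53 ± 0.20). The prolactin receptor Prlr (-0.92 ± 0.18) was lower by less. The kidney androgen-regulated protein Kap (0.54 ± 0.15, adjusted p = 0.0728) and the oxysterol hydroxylase Cyp7b1 (1.26 ± 0.36, adjusted p = 0.0946) were not called. Of 18 measured male-biased kidney genes, 13 rose and 1 fell (16 rose and 1 fell within the list; adjusted p = 4.17e-27, then 0.0176). Measured female-biased kidney genes numbered 14, of which 5 fell and none rose (1 rose and 11 fell within the list; adjusted p = 3.7e-09, then 0.118). Among 16 measured circadian clock genes, 8 rose and 3 fell, with Ciart (1.69 ± 0.27) and Arntl (-1.34 ± 0.24) as examples (9 rose and 3 fell within the list; adjusted p = 0.011, then 0.32). Of 26 measured cell cycle genes, 2 rose and none fell, among them Mcm5 (0.92 ± 0.17) and Mcm3 (0.64 ± 0.16) (12 rose and none fell within the list; adjusted p = 2.69e-10, then 0.333). Adipose markers (4 of 4 up within the list) and erythroid markers shifted up in males with no gene called (medians 3.95 and 1.09; adjusted p = 0.0177 for each, then 0.444 and 0.455), but male 2 stood apart with adipose markers at a sum of 492 CPM (122 to 215 in the other males, 72.5 to 135 in females). Podocyte markers shifted down (-0.16; adjusted p = 0.0448, then 0.444). Called genes numbered 300 without female 1, 301 without female 4 and 311 without male 5, and 785 with DESeq2.

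At 8 weeks (n = 5 per sex) 3169 genes differed, 1614 higher and 1555 lower in males. Of these 389 and 476 differed by at least 2-fold. Among the largest excesses in males were those of Slco1a1 (9.80 ± 0.42, 306 against 0.332), Cyp2j13 (8.70 ± 0.18, 432 against 1.05) and Slc7a13 (8.02 ± 0.21, 1809 against 6.92). The plasma proteins Pzp (7.39 ± 0.31) and Apoh (7.29 ± 0.41), Acsm3 (6.61 ± 0.19) and the hydroxylases Cyp7b1 (6.27 ± 0.15) and Cyp4a12a (5.82 ± 0.21) followed. Odc1 (1.64 ± 0.18), the rate-limiting enzyme of polyamine synthesis, and Kap (1.54 ± 0.21) differed by less. Tbx10 (4.09 ± 0.22) and Esr1 (0.58 ± 0.10) were higher in males, while Ar (-0.16 ± 0.13, adjusted p = 0.395) was not called. Among the largest excesses in females were those of Ugt1a2 (-8.63 ± 0.21, 1.5 against 601) and Slc7a12 (-5.48 ± 0.40, 8.1 against 362), the export pump Abcc3 (-4.23 ± 0.34) and Prlr (-4.01 ± 0.28, 31.7 against 511). The transporters Slc17a2 (-4.94 ± 0.21) and Slc22a29 (-3.64 ± 0.14), kynureninase, Kynu (-2.94 ± 0.22), and the nephron progenitor marker Cited1 (-2.49 ± 0.31) were lower in males as well. Among 18 measured male-biased kidney genes, 17 rose and 1 fell (adjusted p = 3.29e-27, then 0.000279). For female-biased kidney genes, 2 rose and 11 fell of 14 measured (adjusted p = 2.48e-08, then 0.00774). Among 30 measured organic anion and cation transporters, 16 rose and 11 fell, including OAT1, Slc22a6 (1.90 ± 0.12) (adjusted p = 0.0374, then 0.24). Among 34 measured cytochrome P450 genes, 12 rose and 7 fell (12 rose and 8 fell within the list; adjusted p = 0.124 with estimated correlation). Measured proximal tubule S3 markers numbered 10, of which 6 rose and 2 fell (adjusted p = 0.000759, then 0.0282).

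Markers of other tissues and cells moved with sex at 8 weeks too. For adipose markers, 5 fell and none rose of 8 measured, including Adipoq (-4.03 ± 1.19) and Fabp4 (-2.08 ± 0.32) (6 fell and none rose within the list; adjusted p = 2.23e-05, then 0.262). For immune cell markers, 7 fell and none rose of 25 measured, among them Igkc (-2.86 ± 0.68) and Jchain (-2.58 ± 0.68) (adjusted p = 0.00519, then 0.309). For tubule injury genes, 1 rose and 6 fell of 21 measured, among the latter osteopontin, Spp1 (-1.31 ± 0.09) (adjusted p = 0.0203, then 0.262). For skeletal muscle markers, 2 fell and none rose of 3 measured (adjusted p = 0.0123, then 0.0858). Of stromal and matrix markers 4 of 12 fell and none rose (adjusted p = 0.0149, then 0.456), of collecting duct markers 3 of 12 (adjusted p = 0.0123, then 0.124), and of nephron progenitor and developing nephron genes 5 of 10 (adjusted p = 0.0149, then 0.0858). Immediate early and heat shock genes rose in 2 of 12 (adjusted p = 0.0449, then 0.493).

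**Figure D1:**
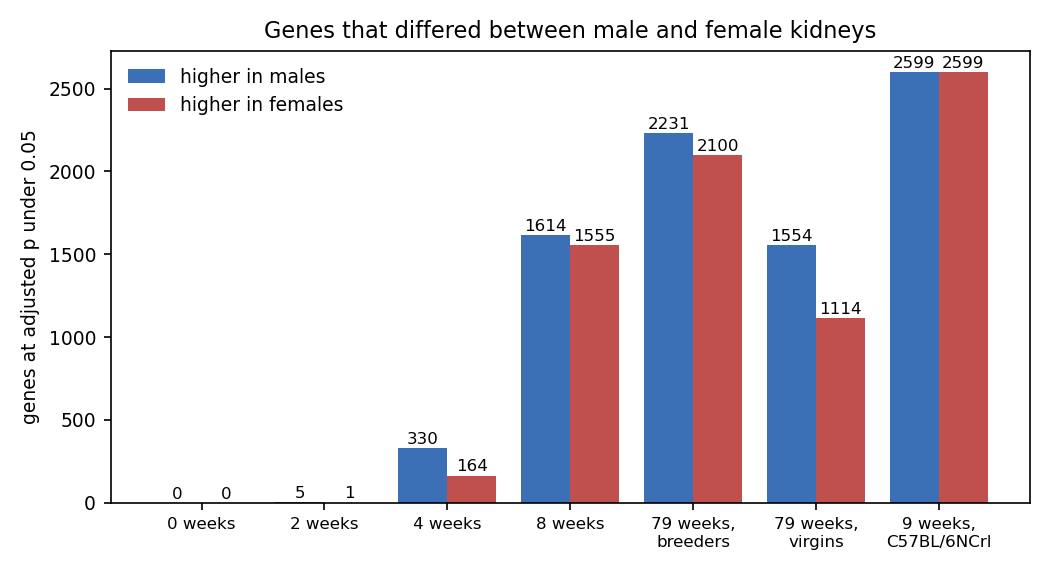
The bars give the number of genes at an adjusted p under 0.05 that were higher in males (blue) or in females (red) at each age in the single-end SMARTer run and, at the right, at 9.29 weeks in the paired-end run. The counts go from 0 at birth to 330 and 164 at 4 weeks and 1614 and 1555 at 8 weeks.

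At 79 weeks the question was whether the difference persists with age, in breeding and in virgin mice, which were fitted together. Among breeders (n = 5 per sex) 4331 genes differed, 2231 higher and 2100 lower in males. Among virgins (n = 4 males and 5 females) 2668 differed, 1554 higher and 1114 lower. In breeders Slc7a13 (8.75 ± 0.34), Cyp2j13 (9.09 ± 0.25), Pzp (9.11 ± 0.37) and Tbx10 (4.18 ± 0.30) were higher in males. Ugt1a2 (-9.01 ± 0.34), Slc17a2 (-6.61 ± 0.39), Slc7a12 (-5.17 ± 0.32) and Prlr (-4.30 ± 0.37) and histidine decarboxylase, Hdc (-7.24 ± 0.64), were lower. In virgins Slc7a13 (8.96 ± 0.35) and Cyp2j13 (8.18 ± 0.25) were higher and Ugt1a2 (-9.14 ± 0.38), Hdc (-7.65 ± 0.72) and Slc17a2 (-6.59 ± 0.42) lower, as was the elongase Elovl3 (-6.92 ± 1.90), at 0.605 to 32.6 CPM over the females. Slc7a12 (-2.44 ± 0.31, 61.6 against 335) and Prlr (-1.74 ± 0.35) were lower in virgin males as well. Neurog2 was read in male breeders and in no female breeder library, with 1.04 ± 0.267 against 0 ± 0 CPM (SD). Measured male-biased kidney genes numbered 18, of which 17 rose and 1 fell among breeders (adjusted p = 2.8e-26, then 0.000693). For male-biased kidney genes, 16 rose and 1 fell of 18 measured among virgins (17 rose and 1 fell within the list; adjusted p = 3.12e-27, then 0.00057). Of 14 measured female-biased kidney genes, 1 rose and 11 fell among breeders (adjusted p = 1.89e-10, then 0.0103). Among 14 measured female-biased kidney genes, 1 rose and 10 fell among virgins (adjusted p = 1.67e-10, then 0.00731). Of 26 measured immune cell markers, 13 fell and none rose among breeders, for example Cd79a (-3.07 ± 0.75) and Lyz2 (-1.30 ± 0.32) (15 fell and none rose within the list; adjusted p = 0.000142, then 0.43). Stromal and matrix markers fell in 6 of 12 among breeders (adjusted p = 0.0041, then 0.409) and 3 among virgins (adjusted p = 0.00367, then 0.422). For collecting duct markers, 4 fell and none rose of 12 measured among virgins (6 fell and none rose within the list; adjusted p = 0.00367, then 0.0437). Female breeder 2 held neither Xist nor Y-linked RNA at the level of its sex, with 2.43 CPM of Y-linked genes (at most 0.312 in the others).

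Breeders were then compared with virgins of the same sex. In females (n = 5 each) 3882 genes were higher and 3583 lower in breeders. In males (n = 5 breeders and 4 virgins) 3413 were higher and 3503 lower. In breeding females Wdfy1 (2.58 ± 0.09) and Bglap3 (1.71 ± 0.30), the B-cell chemokine Cxcl13 (1.70 ± 0.44) and the B-cell gene Ms4a1 (3.34 ± 0.86) rose. Ttc36 (-4.17 ± 0.85), Mrps34 (-3.40 ± 0.77), Fbxl15 (-3.00 ± 0.61) and H2aj (-2.64 ± 0.42) fell in them. In breeding males the chemokine Ccl28 (3.90 ± 0.47) and Wdfy1 (2.65 ± 0.10) rose. So did male-biased genes, Slco1a1 (2.62 ± 0.26, 458 against 74.4) and Acsm3 (1.64 ± 0.26), Odc1 (1.06 ± 0.26) and Kap (0.76 ± 0.18), while female-biased Slc7a12 (-3.06 ± 0.31, 7.43 against 61.6) and Prlr (-2.88 ± 0.36, 14 against 103) fell. The immunoglobulin gene Ighg2c (4.31 ± 1.60) was called with 270 CPM in breeder 1 and 5.5 to 20.4 in the others, and lost the call with a library left out (highest adjusted p = 0.219). Of 18 measured male-biased kidney genes, 12 rose and none fell in breeding males (15 rose and none fell within the list; adjusted p = 0.00216, then 0.923). Among 26 measured immune cell markers, 10 rose and 2 fell in breeding females (adjusted p = 0.926 with estimated correlation). Of 13 measured immediate early and heat shock genes, 7 fell and none rose in breeding males, among them Atf3 (-1.65 ± 0.32) and Jun (-1.20 ± 0.24) (adjusted p = 0.923 with estimated correlation). No list was called by camera in females, where the lowest adjusted p was 0.508. Wdfy1 stood at 107 ± 4.8 (SD) CPM in female and 151 ± 10.8 in male breeders, and at 18.5 ± 2.67 and 24.6 ± 2.12 in virgins. In the 38 libraries of C57BL/6J up to 8 weeks it stood at 23.9 ± 4.4, and in the 10 gonadectomized C57BL/6NCrl libraries at 148 ± 10.7.

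The gap between breeders and virgins differed between the sexes for 12 genes, led by Slc7a12 (-3.06 ± 0.31 in males and -0.33 ± 0.26 in females). Breeding and strain cannot be told apart in it. The difference for Slc7a12 was -2.73 ± 0.40 (adjusted p = 0.0137). The count of 12 was 68 without female breeder 5, 22 without male breeder 4 or male virgin 6, and 20 without female virgin 4. It was 7 without female breeder 2 or female virgin 1, 6 without male breeder 5 or male virgin 9, and 156 with DESeq2. Among 18 measured male-biased kidney genes, none rose or fell for this difference (6 rose and none fell within the list; adjusted p = 2.07e-05, then 0.285).

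In the paired-end SMARTer run, C57BL/6NCrl males and females of 9.29 weeks (n = 6 each) differed in 5198 genes, 2599 higher and 2599 lower in males. Slc7a13 (9.13 ± 0.30, 1079 against 1.93) and Cyp2j13 (9.69 ± 0.39), Acsm3 (8.89 ± 0.35) and Pzp (8.35 ± 0.58) were higher in males, with Slco1a1 (465 against 0.0222 CPM). Ugt1a2 (-8.06 ± 0.46), Slc17a2 (-6.22 ± 0.47) and Hdc (-5.80 ± 0.39) and Slc7a12 (-7.55 ± 0.30, 1.84 against 347) were lower, with Prlr (-5.47 ± 0.21) and Abcc3 (-5.41 ± 0.41). Esr1 (0.69 ± 0.12) was higher and Ar (-0.26 ± 0.09) lower in males. Male-biased kidney genes rose in 17 of 18 and fell in 1 (adjusted p = 6.57e-31, then 0.000144). Female-biased ones rose in 1 of 14 and fell in 11 (adjusted p = 7.77e-13, then 0.00189). Measured stromal and matrix markers numbered 12, of which 9 fell and none rose (10 fell and none rose within the list; adjusted p = 0.116 with estimated correlation). Endothelial, podocyte and skeletal muscle markers fell in 8 of 10, 5 of 8 and 3 of 4 (adjusted p = 0.011, 0.00425 and 0.0132, then 0.285, 0.18 and 0.112), and immediate early and heat shock genes rose in 5 of 14 (adjusted p = 0.00395, then 0.291). Of 8 measured adipose markers, 6 fell and none rose, including Ucp1 (-6.47 ± 1.99), at 156 CPM in female 3 and at most 18.2 in the others (7 fell and none rose within the list; adjusted p = 0.467 with estimated correlation). Among 7 measured erythroid markers, 5 rose and none fell, among them Hba-a1 (1.92 ± 0.51) (5 rose and 1 fell within the list; adjusted p = 0.339 with estimated correlation). Between this comparison and that at 8 weeks, 1259 of 15278 genes rose in both (263 expected if the calls were independent) and 963 fell in both (240 expected).

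Castration asked which male values need the testes. Castrated males given oil (n = 3, 10.3 weeks) differed from intact males (n = 6, 9.29 weeks) in 2725 genes, 1272 higher and 1453 lower. Male-biased genes fell, among them Slco1a1 (-10.36 ± 0.73, 0.361 against 465) and Slc7a13 (-5.71 ± 0.35, 20.6 against 1079) and Cyp2j13 (-8.42 ± 0.50), Acsm3 (-6.73 ± 0.43) and Cyp7b1 (-6.42 ± 0.38). Tbx10 (-4.14 ± 0.43), Cyp4b1 (-3.50 ± 0.19), Kap (-2.49 ± 0.35) and Odc1 (-2.01 ± 0.22) fell too. Female-biased genes rose, led by Ugt1a2 (8.11 ± 0.47, 573 against 2.1), Slc7a12 (6.91 ± 0.30, 222 against 1.84) and Prlr (5.04 ± 0.21, 245 against 7.46). Cyp4a14 (4.73 ± 0.46), Ugt1a10 (4.69 ± 0.28), Abcc3 (4.59 ± 0.42) and Cited1 (3.82 ± 0.46) and renin, Ren1 (1.25 ± 0.28), rose as well. For male-biased kidney genes, 1 rose and 17 fell of 18 measured (adjusted p = 5.08e-38, then 7.6e-05). For female-biased kidney genes, 11 rose and 2 fell of 14 measured (adjusted p = 4.35e-13, then 0.00237). For proximal tubule S3 markers, 1 rose and 6 fell of 10 measured (2 rose and 6 fell within the list; adjusted p = 1.47e-05, then 0.152). Of 11 measured thick ascending limb and distal tubule markers, 4 rose and none fell (adjusted p = 0.00745, then 0.0453). Endothelial and collecting duct markers rose in 4 of 10 and 1 of 12 (adjusted p = 0.0265 and 0.0153, then 0.433 and 0.114), and immediate early and heat shock genes fell in 3 of 14 (adjusted p = 0.0153, then 0.433). Of 7 measured erythroid markers, 5 fell and none rose, among them Hba-a1 (-2.23 ± 0.67) (1 rose and 6 fell within the list, adjusted p = 0.433 with estimated correlation). Neither Ar (0.04 ± 0.11, adjusted p = 0.889) nor Esr1 (-0.10 ± 0.15, adjusted p = 0.759) was called. The calls numbered 1641 and 1763 without castrated oil 2 and 3.

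Ovariectomy (n = 3 with oil against 6 intact females) changed 154 genes, 71 up and 83 down. Ugt1a10 (2.61 ± 0.26) and Cyp4a12a (2.54 ± 0.35) and Slc7a13 (2.41 ± 0.26, 10.3 against 1.93) rose, and so did Esr1 (0.64 ± 0.15). Ccl28 (-5.07 ± 0.85), the immunoglobulin gene Igha (-3.33 ± 0.73) and Sec14l3 (-3.22 ± 0.58), Akr1c18 (-2.59 ± 0.59) and Hdc (-2.46 ± 0.42) fell. Measured circadian clock genes numbered 16, of which 7 rose and 2 fell, including Ciart (2.28 ± 0.46), Per2 (2.07 ± 0.23) and Dbp (1.87 ± 0.22) (10 rose and 2 fell within the list; adjusted p = 1.64e-09, then 0.00951). Among 26 cell cycle genes, 4 fell and none rose, including Ccnb1 (-1.74 ± 0.42), Birc5 (-1.72 ± 0.36) and Cdk1 (-1.62 ± 0.34) (18 fell and none rose within the list; adjusted p = 7.22e-16, then 0.00951). Immune cell markers, stromal and matrix markers and tubule injury genes shifted down with no gene called (medians -0.27, -0.47 and -0.28; adjusted p = 0.0205, 0.0214 and 0.0254, then 0.775, 0.723 and 0.723). Calls numbered 78 without intact female 4 and 100, 41 and 58 without ovariectomized oil 1, 2 and 3, and 435 with DESeq2.

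Testosterone at 15 mg/kg, given to castrated males 24 h before collection (n = 3 each), changed 443 genes, 198 up and 245 down. Male-biased genes rose, among them Cyp2j13 (5.53 ± 0.46) and Slco1a1 (4.96 ± 0.64) and Tbx10 (3.87 ± 0.45, 11.5 against 0.791) and Slc7a13 (3.46 ± 0.32, 227 against 20.6). Cyp4b1 (2.13 ± 0.19), Acsm3 (1.76 ± 0.36), Cyp2e1 (1.58 ± 0.27) and Odc1 (0.90 ± 0.23) rose too. The immunoglobulin gene Igkc (4.11 ± 1.01) was called, but treated 2 stood apart, with Igkc at 117 CPM (4.12 and 4.17 in the other treated) and the immune cell marker Lyz2 at 330 (26 and 30.4), and Igkc lost the call with a library left out (highest adjusted p = 0.669). Cox5a (-3.40 ± 0.76), Rgcc (-3.17 ± 0.81), Il17rc (-3.05 ± 0.67), Acaa1b (-2.66 ± 0.39) and Apoe (-2.63 ± 0.55) and Prlr (-1.51 ± 0.24) fell. Neither Kap (0.58 ± 0.35, adjusted p = 0.528) nor Slc7a12 (-0.51 ± 0.31, adjusted p = 0.533) was called. Of 18 measured male-biased kidney genes, 11 rose and none fell (14 rose and none fell within the list; adjusted p = 1.5e-26, then 0.000728). Of 14 measured female-biased kidney genes, 3 fell and none rose (9 fell and none rose within the list; adjusted p = 2.38e-06, then 0.0688). Measured immune cell markers numbered 26, of which 2 rose and none fell, with treated 2 included (11 rose and none fell within the list; adjusted p = 5.7e-07, then 0.296). Stromal and matrix markers and erythroid markers shifted up with no gene called (medians 0.52 and 1.51; adjusted p = 0.00797 and 0.0014, then 0.306 and 0.296). Among 34 measured peroxisome and fatty acid oxidation genes, 2 rose and 3 fell (3 rose and 14 fell within the list; adjusted p = 5.1e-05, then 0.296). Called genes numbered 178 and 216 without castrated oil 2 and 3, 286 and 197 without treated 1 and 2, and 7.7e+02 (rounded) with DESeq2.

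In ovariectomized females (n = 3 each) testosterone changed 44 genes, 40 up and 4 down. Cyp2j13 (4.31 ± 0.46), Ugt2b37 (3.50 ± 0.33) and Tbx10 (3.10 ± 0.44) and Slc7a13 (2.67 ± 0.32, 65.6 against 10.3) rose, with Slco1a1 (1.73 against 0.0169 CPM). Hdc (-2.32 ± 0.47) and Alas1 (-1.31 ± 0.24) and the fatty acid binding protein Fabp1 (-1.50 ± 0.28) fell. Among 18 measured male-biased kidney genes, 6 rose and none fell (11 rose and none fell within the list; adjusted p = 1.82e-20, then 0.00318). Adipose markers shifted up with no gene called (median 1.79; adjusted p = 0.00573, then 0.683). The calls numbered 20 without oil 2 or oil 3, 91 without treated 1, 26 without treated 3 and 175 with DESeq2. For the difference between this effect and that in castrated males (4 groups of n = 3) edgeR called no gene, with 1514 at an unadjusted p under 0.05 and 90 called by DESeq2. Without ovariectomized treated 1 edgeR called 12. None of 18 male-biased kidney genes rose or fell differently between the sexes (adjusted p = 0.00358, then 0.8).

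Between castrated males and ovariectomized females given oil (n = 3 each) 9 genes differed. The Y-linked genes were higher in males, and Xist, Kdm6a (-1.29 ± 0.21), which escapes X inactivation, Hdc (-2.66 ± 0.48) and Cdk13 (-0.67 ± 0.12) lower. All 4 Y-linked genes rose (adjusted p = 9.16e-09 with estimated correlation). Of 5 measured X-linked genes escaping inactivation, 2 fell and none rose (5 fell and none rose within the list; adjusted p = 0.00255 with estimated correlation). For male-biased kidney genes, none rose or fell of 18 measured (5 rose and 1 fell within the list; adjusted p = 0.00154, then 0.426). For stromal and matrix markers, none rose or fell of 12 measured (4 fell and none rose within the list; adjusted p = 0.000119, then 0.252). The count of called genes was 5 without castrated oil 1 or ovariectomized oil 2, 12 without ovariectomized oil 1 and 62 with DESeq2.

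In the single-end run a smaller experiment at 11 weeks compared testosterone (n = 4) with oil (n = 2) over both gonadectomized sexes, with sex as a term. It called 259 genes, 161 up and 98 down. Cyp2j13 (6.31 ± 0.37), Ugt2b37 (4.74 ± 0.19), Tbx10 (4.20 ± 0.24) and Slc7a13 (4.02 ± 0.17) rose, with Slco1a1 (13.9 against 0.022 CPM). Padi2 (-2.26 ± 0.22), Hsd17b14 (-2.15 ± 0.18), Bhmt (-2.02 ± 0.23), Abcc3 (-1.62 ± 0.11) and Prlr (-1.50 ± 0.22) fell. Of 18 measured male-biased kidney genes, 12 rose and none fell (15 rose and none fell within the list; adjusted p = 1.52e-20, then 0.518). Of 161 genes up here, 94 also rose in castrated males of the paired-end run (1.96 expected), and of 98 down, 34 fell there (1.49 expected). Called genes numbered 21 without castrated oil and 74 without ovariectomized oil, each the lone oil library of its sex. They numbered 148 and 123 without ovariectomized treated 1 and 2, 697 and 744 without castrated treated 1 and 2, and 405 with DESeq2.

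**Figure D2:**
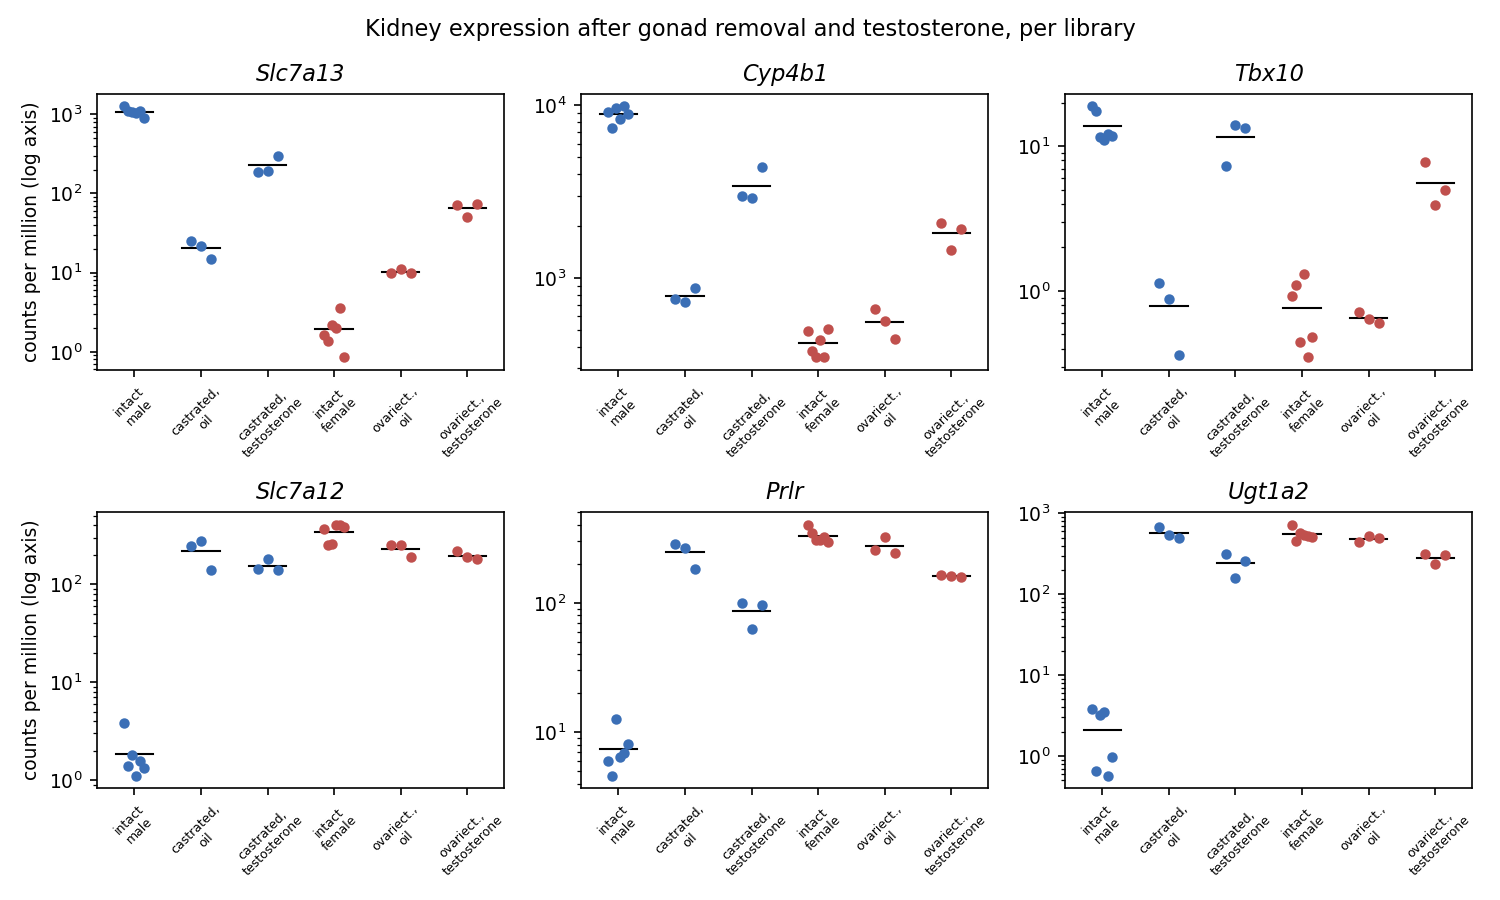
Each point is 1 library of the paired-end SMARTer run, blue for males and red for females, with its CPM on a log axis, and each black line is the mean of its group. In castrated males given oil Slc7a13 stands at a mean of 20.6 and with testosterone at 227, and Slc7a12 at 222 against 1.84 in intact males.

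Deletion of Ar in the nephron of males asked which male values need the receptor there (n = 4 against 6 controls). Ar stood at 6.16 ± 1.61 against 69 ± 6.4 CPM (SD), -3.48 ± 0.16 on the log2 scale, with every deleted library below every control. In all 5425 genes changed, 2684 up and 2741 down. Slco1a1 (-4.90 ± 0.35, 8.01 against 239) and Slc7a13 (-4.02 ± 0.15, 34.2 against 553) and Cyp7b1 (-4.52 ± 0.27), Pzp (-4.26 ± 0.24) and Acsm3 (-4.08 ± 0.17) fell. Tbx10 (-3.28 ± 0.20), Cyp4b1 (-3.03 ± 0.16), Kap (-2.61 ± 0.16) and Odc1 (-1.50 ± 0.14) fell too. Ugt1a2 (7.14 ± 0.50, 191 against 1.36) and Slc7a12 (5.03 ± 0.34, 207 against 6.36) and Ugt1a10 (4.51 ± 0.24), Cyp4a14 (3.78 ± 0.28), Prlr (3.70 ± 0.36) and Kynu (2.57 ± 0.20) rose. The immunoglobulin gene Ighg1 (5.04 ± 0.92), at 3.13 to 44.6 CPM over the deleted males, the monocyte chemokine Ccl2 (2.53 ± 0.40) and the macrophage lysozyme Lyz2 (2.25 ± 0.33) rose as well. Among 18 measured male-biased kidney genes, 17 fell and none rose (adjusted p = 6.81e-21, then 0.0531). Among 14 measured female-biased kidney genes, 9 rose and 2 fell (adjusted p = 0.00065, then 0.4). Of 21 measured tubule injury genes, 16 rose and none fell, among them Vcam1 (1.39 ± 0.21) and Spp1 (1.38 ± 0.07) (18 rose and 1 fell within the list; adjusted p = 3.07e-06, then 0.4). For immune cell markers, 17 rose and none fell of 25 measured, among them Cd4 (1.64 ± 0.22) and H2-Ab1 (1.01 ± 0.14) (20 rose and none fell within the list; adjusted p = 2.39e-06, then 0.532). Of 10 measured proximal tubule S3 markers, 8 fell and none rose (adjusted p = 3.42e-07, then 0.4). Measured organic anion and cation transporters numbered 30, of which 7 rose and 16 fell (7 rose and 17 fell within the list; adjusted p = 0.0109, then 0.619). Collecting duct and endothelial markers rose in 4 of 12 and 4 of 10 (adjusted p = 0.0366 and 0.0387, then 0.532 and 0.619). Of 12 measured stromal and matrix markers, 2 rose and none fell (8 rose and none fell within the list; adjusted p = 0.00548, then 0.619).

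In females (n = 5 against 6 controls) the same deletion left Ar at 4.84 ± 1.31 against 64.1 ± 16.1 CPM (SD; -3.73 ± 0.22, adjusted p = 7.22e-07). The other 5 calls were immunoglobulin genes that rose, listed after their values were seen: Ighv1-55 (2.75 ± 0.42), Ighv14-2 (2.90 ± 0.42), Ighv8-12 (2.86 ± 0.43), Igkv1-135 (3.05 ± 0.38) and Igkv5-39 (3.99 ± 0.58). No other gene of the kidney panel was called, with Slc7a12 (-0.13 ± 0.12, adjusted p = 1) and Slc7a13 (-1.06 ± 0.28, adjusted p = 0.506) as examples. Measured male-biased kidney genes numbered 17, of which none rose or fell (1 fell and none rose within the list; adjusted p = 0.899). None of 14 female-biased kidney genes rose or fell (adjusted p = 0.0344, then 0.397). Camera called lists on small shifts, such as the markers of proximal tubule segments S1 and S2 with a median log2 fold change of 0.19 (adjusted p = 6.45e-05, then 0.335). Immune cell markers had a median of 0.09 (adjusted p = 0.00137, then 0.525). The calls numbered 31 without deleted 1, 1 without deleted 5 or control 1, 2 or 5, 2 without deleted 4 or control 4, and 64 with DESeq2. The effect in females was not tested against that in males, which came from another run.

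Deletion of Esr1 in the nephron asked the same of the estrogen receptor. In females (n = 6 against 3) Esr1 stood at 3.63 ± 0.905 (SD) against 5.95 ± 0.892 CPM, and Esr1 (-0.75 ± 0.18, adjusted p = 0.382) was not called. EdgeR called no gene, with 1344 at an unadjusted p under 0.05 and 95 called by DESeq2. It called 7 without control 1 and 1 without control 3 or deleted 6. Of 25 measured immune cell markers, none rose or fell (4 rose and none fell within the list; adjusted p = 4.02e-06, then 0.952). Stromal and matrix markers shifted up as well (median 0.55; adjusted p = 0.00264, then 0.952). In males (n = 3 each) Esr1 (-2.07 ± 0.18, 3.39 against 14.2) fell, and 14 genes were called, 11 up and 3 down. Genes of fat cells rose, Adipoq (4.78 against 0 CPM), Cfd (23 against 0.013 CPM) and Plin1 (11.3 against 0.00918 CPM) and Cidec (5.25 ± 0.43) and Car3 (2.42 ± 0.18), and Ceacam2 (-1.37 ± 0.18) and Fam107a (-1.14 ± 0.11) fell. The remaining rises, listed after their values were seen, were Retn (5.57 ± 0.55), Slc36a2 (5.54 ± 0.46), Dio2 (4.96 ± 0.60), Hp (3.64 ± 0.47) and Plin4 (2.06 ± 0.27) and Otop1, at 0 counts in every control. Among 8 measured adipose markers, 5 rose and none fell (8 rose and none fell within the list; adjusted p = 3.14e-34, then 0.00558). Among 25 measured immune cell markers, none rose or fell (9 rose and none fell within the list; adjusted p = 4.21e-12, then 0.213). Tubule injury genes and stromal and matrix markers shifted up with no gene called (medians 0.40 and 0.62; adjusted p = 0.000293 and 0.00193, then 0.405 and 0.674). The count of called genes was 34 without deleted 1, 9 without deleted 2 or control 2 and 97 with DESeq2.

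In the paired-end run 3 males and 1 female labelled with deletion of Esr1 (n = 4) were compared with 6 controls, with sex as a term. EdgeR called no gene, with 429 at an unadjusted p under 0.05 and 41 called by DESeq2, and Esr1 (-0.35 ± 0.38, adjusted p = 1) was not called. The library labelled deleted female 1 held 478 counts of Esr1 and 158 of Ar, where the control females held 1350 to 2844 of Ar. The library labelled control female 1 held 0 counts of Xist and 4 of the Y-linked genes.

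Kidneys without Ar in any tissue were compared, within the kidney and liver poly-A run, with males of the Tbx10 and Neurog2 lines (n = 5 against 10), which are another cross and 8.14 to 13.4 weeks old against 10.6 to 17. Each deleted library held 0 or 1 count of Ar, against a mean of 90.0 CPM. In all 7491 genes changed, 3770 up and 3721 down. Slco1a1 (-10.43 ± 0.53, 0.267 against 378) and Cyp2j13 (-8.76 ± 0.36), Cyp7b1 (-6.46 ± 0.19), Slc7a13 (-5.97 ± 0.39) and Kap (-3.76 ± 0.25) fell. Ugt1a2 (9.23 ± 0.25), Slc7a12 (5.14 ± 0.65), Cyp4a14 (4.53 ± 0.55) and Prlr (4.07 ± 0.52) and betaine-homocysteine methyltransferase, Bhmt (4.02 ± 0.34), rose. For male-biased kidney genes, 2 rose and 17 fell of 19 measured (adjusted p = 8.48e-21, then 0.000577). For female-biased kidney genes, 10 rose and 2 fell of 14 measured (adjusted p = 1.41e-05, then 0.0375). Of 12 measured collecting duct markers, 10 rose and none fell, such as Foxi1 (0.77 ± 0.12) (adjusted p = 0.000126, then 0.0375). For nephron progenitor and developing nephron genes, 7 rose and none fell of 15 measured (8 rose and none fell within the list; adjusted p = 0.00208, then 0.019). Of 8 measured podocyte markers, 6 rose and none fell, such as Wt1 (1.22 ± 0.10) (adjusted p = 0.361 with estimated correlation). Tubule injury genes (adjusted p = 0.0194, then 0.361) rose in 6 of 21. For endothelial markers, 8 rose and none fell of 10 measured (adjusted p = 0.234 with estimated correlation). Ribosomal RNA genes took 12.4 to 17.8% of counts in the deleted kidneys and 1.68 to 7.4% in the others of the run.

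Of 2613 genes lower after the nephron deletion of Ar in males, 2088 were also lower without Ar in any tissue (567 expected if independent) and 14 higher. Of 2562 higher genes, 1425 were also higher (549 expected) and 31 lower. Castration, in yet another run, shared 1123 lower genes with the nephron deletion (226 expected) and 706 higher genes (187 expected).

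The Tbx10 and Neurog2 lines asked whether these male-biased factors shape the difference between the sexes, and the run held no kidney without a deletion label. In the Tbx10 line (n = 7 males and 4 females) 4409 genes differed between the sexes, and in the Neurog2 line (n = 3 males and 5 females) 3181. Among the largest excesses in males were those of Slco1a1 (9.95 ± 0.56), Slc7a13 (8.28 ± 0.49) and Cyp2j13 (8.16 ± 0.39) in the Tbx10 line and Slc7a13 (8.60 ± 0.47), Slco1a1 (7.90 ± 0.46) and Acsm3 (7.64 ± 0.44) in the Neurog2 line. Females led in Ugt1a2 (-8.93 ± 0.24) and Slc7a12 (-5.47 ± 0.68) and in Ugt1a2 (-10.06 ± 0.38) and Slc17a2 (-7.22 ± 0.90), in the same order. Over both sexes Tbx10 stood at 0.15 ± 0.0955 against 2.21 ± 2.69 CPM (SD) in the Tbx10 against the Neurog2 line, -3.43 ± 0.34. Between the sexes Tbx10 (1.34 ± 0.52, adjusted p = 0.0675) was not called in the Tbx10 line and Tbx10 (4.04 ± 0.45) was higher in males of the Neurog2 line; these differences were not tested against each other. Neurog2 (-0.35 ± 0.89, adjusted p = 0.842) was not called between the lines, and males of the Neurog2 line held 58 to 153 counts of it. Of 19 measured male-biased kidney genes, 17 rose and 2 fell in the Tbx10 line (adjusted p = 5.9e-27, then 9.88e-05). Among 19 measured male-biased kidney genes, 17 rose and 2 fell in the Neurog2 line (adjusted p = 2.78e-26, then 6.45e-05). Of 14 measured female-biased kidney genes, 11 fell and none rose in the Tbx10 line (adjusted p = 5.12e-11, then 0.00201). Among 14 measured female-biased kidney genes, 11 fell and none rose in the Neurog2 line (12 fell and none rose within the list; adjusted p = 2.36e-16, then 0.000278). Collecting duct markers fell in 7 of 12 in the Tbx10 line (adjusted p = 0.000924, then 0.0674) and 5 in the Neurog2 line (adjusted p = 0.00345, then 0.0924), and podocyte markers in 6 of 8 in the latter (adjusted p = 0.000135, then 0.214). Among 8 measured podocyte markers, 7 fell and none rose in the Tbx10 line (adjusted p = 0.000141, then 0.199). The count of called genes in the Neurog2 line was 2089 without male 2.

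Between the lines (n = 11 against 8, sex as a term) 3193 genes differed. Hba-a2 (3.09 ± 0.55) and Rpl26 (1.59 ± 0.34) were higher in the Tbx10 line and Eno1b (-5.76 ± 0.61), Angptl7 (-4.91 ± 0.39), Greb1 (-4.28 ± 0.53) and Ugt1a10 (-3.90 ± 0.23) lower. For erythroid markers, 4 rose and none fell of 6 measured (adjusted p = 0.00713, then 0.752). Measured male-biased kidney genes numbered 19, of which 2 rose and 1 fell, and of 14 measured female-biased kidney genes 3 rose and 1 fell.

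The genes that differed by at least 2-fold at 8 weeks in the single-end run, 384 male-biased and 475 female-biased, were followed as sets through libraries that did not define them. The median log2 fold change of the male-biased set was 1.41 between the sexes at 9.29 weeks, where 327 rose, and -1.41 after castration, where 312 fell. After the deletion of Ar it was -1.08 in the nephron of males (298 fell), -1.42 throughout the body (291 fell) and 0.01 in the nephron of females. With testosterone it was 0.63 in castrated males (109 rose) and 0.35 in ovariectomized females (28 rose). The median of the female-biased set was -1.22 at 9.29 weeks, 0.85 after castration, 0.71 after either deletion of Ar in males and -0.31 after ovariectomy. In the Tbx10 and Neurog2 lines the male-biased set had medians of 1.26 and 1.12 between the sexes.

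**Figure D3:**
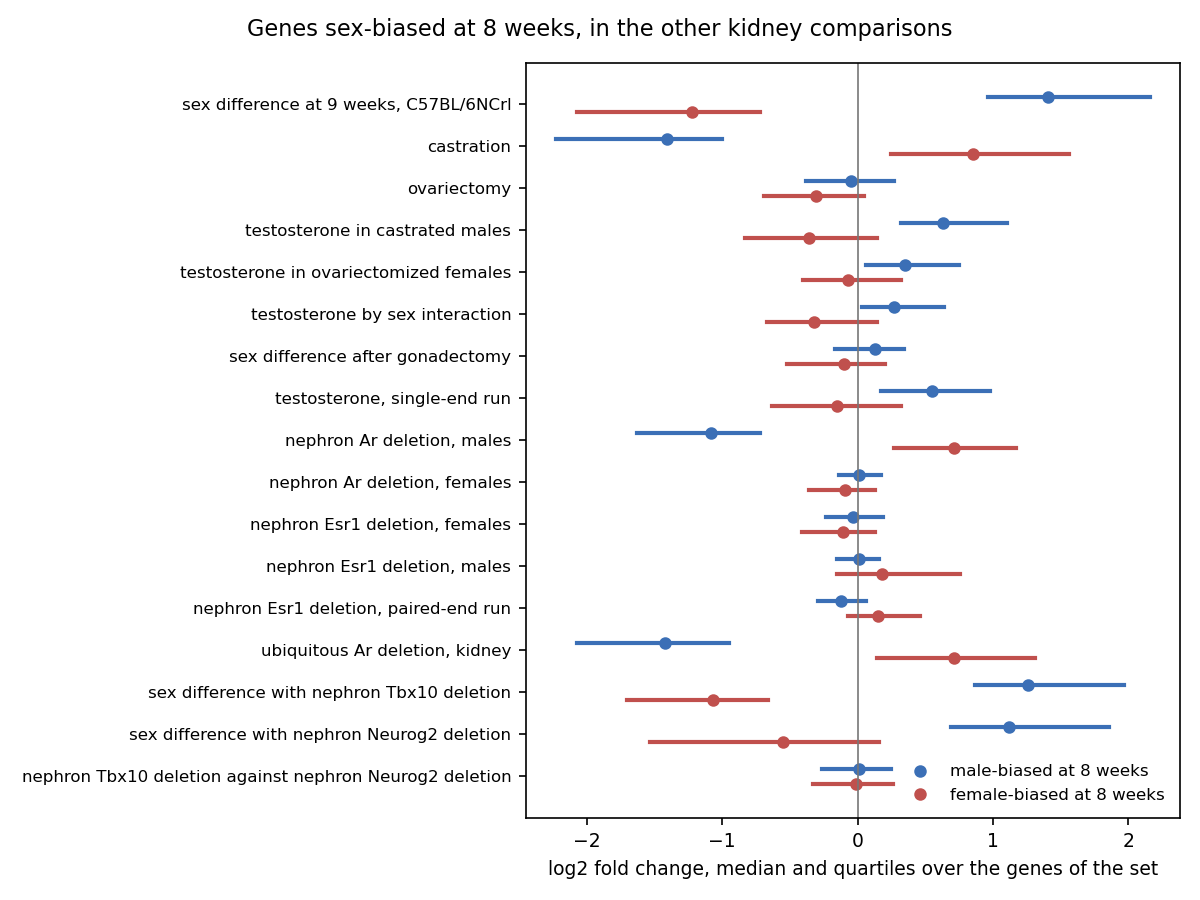
For each kidney comparison that did not define the sets, a dot marks the median log2 fold change of the genes male-biased (blue) or female-biased (red) at 8 weeks, and a line joins the quartiles over the genes. The male-biased set lies at 1.41 between the sexes at 9.29 weeks and at -1.41 after castration.

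In liver, deletion of Ar in hepatocytes of males (n = 5 each) asked what the receptor does there. Ar had 68 to 422 counts per control library and 2 to 26 per deleted library (-5.05 ± 0.59), with 68 in control 4. In all 1478 genes changed, 664 up and 814 down. The clock repressor Ciart (-3.57 ± 0.60), the zinc-finger factor Zbtb16 (-2.85 ± 0.42), Usp2 (-2.80 ± 0.51) and Fkbp5 (-2.04 ± 0.27), a co-chaperone of steroid receptors, fell. The heat shock gene Hspa1b (-1.54 ± 0.33) and the major urinary protein Mup1 (-1.27 ± 0.20) fell too. The sterol regulator Srebf1 (1.12 ± 0.27), Pdk4 (1.27 ± 0.25), a kinase that restrains glucose oxidation, and Tubb2a (1.60 ± 0.35), Nr4a1 (1.53 ± 0.42) and Neat1 (1.46 ± 0.19) rose. The male-biased Mup20 (-0.21 ± 0.21, adjusted p = 0.609), Cyp2d9 (-0.31 ± 0.12, adjusted p = 0.112) and Elovl3 (-0.02 ± 0.32, adjusted p = 0.983) were not called. Measured peroxisome and fatty acid oxidation genes numbered 33, of which 1 rose and 15 fell, among them Cpt1a (-0.64 ± 0.09) and Pex11a (-0.96 ± 0.14) (2 rose and 18 fell within the list; adjusted p = 3.13e-05, then 0.217). For cholesterol synthesis genes, 8 rose and none fell of 22 measured, such as Hmgcs1 (0.82 ± 0.18) (9 rose and none fell within the list; adjusted p = 0.00159, then 0.644). For circadian clock genes, 1 rose and 7 fell of 16 measured (2 rose and 9 fell within the list; adjusted p = 0.00353, then 0.217). For male-biased liver genes, 2 rose and 3 fell of 26 measured (2 rose and 14 fell within the list; adjusted p = 0.0109, then 0.293). Immune cell markers rose in 2 of 26 and cell cycle genes in 1 of 25 (adjusted p = 0.01 and 0.0459, then 0.644 for each). Among 22 measured female-biased liver genes, 2 rose and 2 fell (adjusted p = 0.89). The deleted mice were 10.6 weeks old and the controls 11.3 to 12.4, and with age as a term 414 genes were called. Called genes numbered 907 without deleted 2 or control 3 and 954 without deleted 4.

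Livers of males without Ar in any tissue (n = 5) were compared with control female livers (n = 4) of the same run, which asks how much of the difference between the sexes is left. In all 319 genes differed, 159 higher and 160 lower in the deleted males. The steroid sulfotransferase Sult2a1 (-9.25 ± 1.08, 0.288 against 172) and Cyp3a41b (-4.41 ± 0.82), Cyp3a41a (-4.03 ± 0.63) and Cyp17a1 (-3.39 ± 0.48) were lower in those males, and Bhlhe41 (3.41 ± 0.56), Inhbe (2.16 ± 0.29), Mup21 (1.75 ± 0.30) and Thrsp (1.52 ± 0.27) higher. The sex-biased Cyp2b9 (-0.94 ± 0.26, adjusted p = 0.102), Cyp2d9 (2.60 ± 0.66, adjusted p = 0.1) and Mup20 (1.92 ± 0.59, adjusted p = 0.161) were not called. Of 26 measured male-biased liver genes, 3 rose and none fell (12 rose and none fell within the list; adjusted p = 5.48e-10, then 0.331). Measured female-biased liver genes numbered 33, of which 8 fell and none rose (13 fell and none rose within the list; adjusted p = 7.81e-11, then 0.331). Among 19 measured lipogenesis genes, 3 rose and none fell (7 rose and none fell within the list; adjusted p = 5.01e-05, then 0.347). Measured genes of gluconeogenesis and amino acid catabolism numbered 16, of which 2 fell and none rose, Pck1 (-0.92 ± 0.20) and Tat (-0.95 ± 0.18) (3 fell and none rose within the list; adjusted p = 0.000236, then 0.36). The deleted males were 10.6 to 17 weeks old and the females 8.43, ribosomal RNA took 16.3 to 22.1 and 0.431 to 36.9% of counts, and with age as a term 515 genes were called. The calls numbered 73 and 164 without deleted 2 and 3, 85, 62, 107 and 172 without control females 1, 2, 3 and 4, and 8.9e+02 (rounded) with DESeq2.

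Control males were in the liver poly-A run only, so sex and run, and deletion and run, cannot be told apart in the comparisons that follow. Control male (n = 5) against control female livers (n = 4) gave 3970 genes, and livers of males without Ar (n = 5) against control males 2442. In control males Mup20 (6.62 ± 0.57, 3235 against 32.8) and Mup7 (8.99 ± 1.07), Hsd3b5 (7.01 ± 0.81), Elovl3 (6.05 ± 1.16) and Cyp2d9 (5.81 ± 0.56) were higher. Cyp2b9 (-11.06 ± 0.89, 0.272 against 606) and Cyp2b13 (-11.76 ± 1.06), Cyp3a41a (-5.38 ± 0.53) and Cux2 (-5.26 ± 0.86) were lower, Cux2 being a female-enriched transcription factor of liver. In males without Ar Mup7 (-10.10 ± 1.01), Mup20 (-4.71 ± 0.47), Elovl3 (-3.99 ± 0.92) and Cyp2d9 (-3.22 ± 0.45) were lower than in control males and Cyp2b13 (10.79 ± 1.04), Cyp2b9 (10.12 ± 0.86), Cux2 (5.60 ± 0.85) and Prlr (2.36 ± 0.31) higher. Among 27 measured male-biased liver genes, 25 rose and none fell between the control sexes (26 rose and none fell within the list; adjusted p = 1.07e-28, then 0.00113). Measured male-biased liver genes numbered 27, of which 22 fell and none rose with the deletion (25 fell and none rose within the list; adjusted p = 4.11e-25, then 0.00219). For female-biased liver genes, 30 fell and none rose of 33 measured between the control sexes (31 fell and none rose within the list; adjusted p = 1.06e-33, then 0.000506). Of 33 measured female-biased liver genes, 24 rose and 1 fell with the deletion (30 rose and 1 fell within the list; adjusted p = 8.43e-27, then 0.0017). Among 16 measured genes of the growth hormone and STAT5 pathway, 5 fell and none rose between the control sexes (adjusted p = 0.0139, then 0.0516). Markers of other cells moved too. Measured immune cell markers numbered 26, of which 8 fell and none rose between the control sexes (1 rose and 9 fell within the list; adjusted p = 0.00129, then 0.521), and of 26 cell cycle genes 5 fell (adjusted p = 0.00145, then 0.521). For immune cell markers, 5 rose and none fell of 26 measured with the deletion (10 rose and none fell within the list; adjusted p = 9.69e-05, then 0.314), and of 6 erythroid markers 2 fell (adjusted p = 0.0072, then 0.334). The peroxisome and fatty acid oxidation list was called between the control sexes with a median of 0.22 and a mean of -0.08 (adjusted p = 0.0139, then 0.715). It was called with the deletion with a median of -0.27 and a mean of 0.17 (adjusted p = 0.0226, then 0.804).

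**Figure D4:**
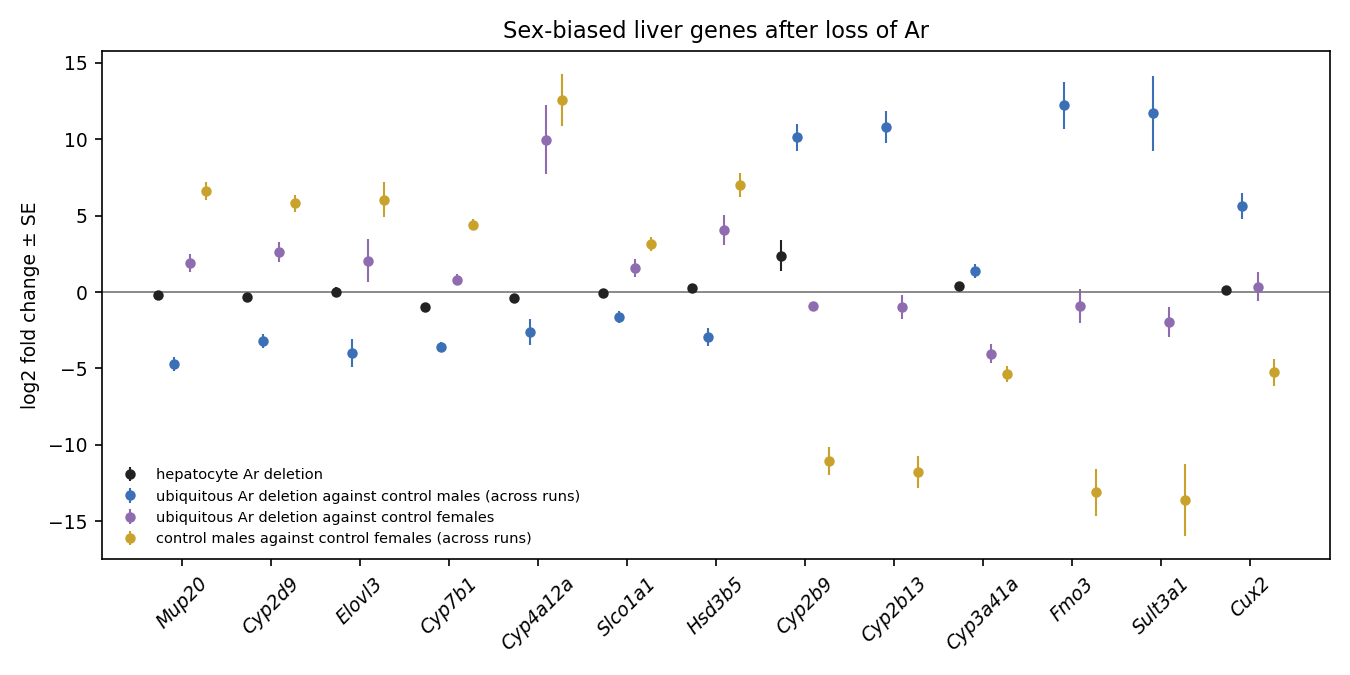
Points give the log2 fold change of 13 sex-biased liver genes in each of the 4 liver comparisons, and bars give ± 1 standard error; the hepatocyte deletion lacks points for genes not tested there. The most extreme points, such as Sult3a1 and Fmo3, rest on a group at or near 0 counts, and the comparisons across runs mix sex or deletion with run.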

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

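The tests of abundant RNAs, of a wrong sex label and of the fat markers in the paired-end run, and the fits without doubted libraries, were chosen only after the results were seen.

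Breeders and virgins of 79 weeks differed in 7465 genes in females and 6916 in males. Without composition scaling 3926 genes were higher and 3476 lower in breeding females, and 3337 and 3450 in males, which argues against a few abundant RNAs as the whole cause, since these would move the other genes one way. Of 9 genes that parted C57BL/6J libraries from gonadectomized C57BL/6NCrl ones of this run, 66.7% lay nearer to C57BL/6J in the virgins of each sex (Gm28438, Wdfy1, Gm15446, Gm42031, Lrmda and Plac9a) and 0.0% in the breeders. Different strains behind the breeder and virgin labels may add to the calls but cannot be told apart from breeding history. F5, Stmn1 and Serpina6 lay nearer to C57BL/6NCrl in both and cannot decide, and marker libraries differ in age and surgery. Nnt, looked up after its values were seen and known to be deleted in part in C57BL/6J, stood at 184 CPM in C57BL/6J, 550 in gonadectomized C57BL/6NCrl, 388 and 409 in female and male breeders, and 233 and 217 in virgins.

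At birth edgeR called 0 genes, though a single fit of all 12 intact groups called 1991. The library labelled female 3a lay apart with Xist at 0.1 CPM (196 to 218 in the other females) and Y-linked genes at 262 (0.625 to 1.51). Leaving it out gave 5 calls, as a library with the wrong sex label would, and leaving out 3b as well gave 9, which cannot tell another library batch from that label, since 3a is left out in both. Both held more ribosomal RNA (1.78 and 1.94%) than the other newborns (0.251 to 0.364%). With a real count of 0, all 35 splits reach it, which tests nothing, and no biological explanation was tested.

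Fat cell genes were among the 14 calls with loss of Esr1 in males of the DNBseq run. The ranks of the 8 adipose markers in each deleted library correlated with those in the library of another group that had them highest, at 0.71 or more, consistent with fat tissue left on the kidneys. The sum of the markers was 115 to 144 CPM in the deleted males and 17.9 to 30.1 in their controls, but reached 425 in a control male of the Ar cross. Loss of Esr1 itself stays open. In the paired-end run the markers had a median log2 fold change of 0.86 (mean 0.81, camera adjusted p = 0.888). The 95% interval of 0.48 to 1.15 is over genes, not libraries, and no Esr1 loss was measured there (-0.35 ± 0.38). The 10 splits are too few for a share under 0.05 (14 calls and up to 151 in other splits, of which 2 in all reached 14), and the larger count points to a structure of the samples.

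Other splits of libraries tested each call count, given as the real one and the highest of the others. Some were reached by the real split alone (1 of 56 to 100, unadjusted), leaving run and strain open. This held for sex at 2 (6, sex-linked, and 1), 4 (494 and 130) and 8 weeks (3169 and 1). It held at 79 weeks in breeders (4331 and 826) and virgins (2668 and 1100) and at 9.29 weeks (5198 and 1778). It held for the breeder label in females (7465 and 368), males (6916 and 5044) and their difference (12 and 4). It held for castration (2725 and 106) and ovariectomy (154 and 85). It held for loss of Ar in the male nephron (5425 and 90) and in all tissues (7491 and 1607), and for sex in the Tbx10 (4409 and 190) and Neurog2 lines (3181 and 501) and the lines' difference (3193 and 550). In livers it held for the loss in hepatocytes (1478 and 1), deleted males against females (319 and 25), and across runs the control sexes (3970 and 1904) and the loss in males (2442 and 126). With loss of Ar in females 4 of 100 splits reached the count (6 and 19). This unadjusted share does not exclude chance for the count, and a split with 19 calls points to a structure of the samples. A real count of 0 is reached by every split and so tests nothing for the testosterone effect by sex (60 splits; 0 and 236) and the Esr1 deletion label in females (84; 0 and 119) and in the paired-end run (80; 0 and 164), where the larger counts point to a structure of the samples. With 10 splits each, those for testosterone in castrated males (443 and 2) and ovariectomized females (44 and 42) and for sex after gonadectomy (9 and 0) are too few for a share under 0.05.

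A library lay far from the others of its group in 16 of 178 sets of values tested, and chance alone gives about 1 in 20. Y-linked genes stood apart at 0.76 CPM in female 5 of 2 weeks (0.196 to 0.35 in the others), 2.43 in female breeder 2 (0 to 0.312), 0.12 in Esr1-deleted female 6 of the DNBseq run (0 to 0.0276) and 0.0372 in Ar-deleted female 2 (0 in the others). Female 1 of the Neurog2 line held Y-linked genes at 0.288 (0.0196 to 0.0636) and Xist at 710 CPM (624 to 642). Female virgin 3 held Esr1 at 8.58 (7.58 to 7.73) and Xist at 105 (64 to 73.6), and female 1 of 8 weeks held Esr1 at 15.1 (12.6 to 13.2). Ar stood at 106 in male 1 of 4 weeks (67.7 to 76) and at 0.0211 in liver 1 without Ar in any tissue (0 in the others). Tbx10 stood at 1.03 in female control 4 of the Ar cross (0.204 to 0.405) and at 0.0973 in kidney 4 without Ar (0.25 to 0.308), and Esr1 at 13.5 in kidney 5 without Ar (21.1 to 23.9).

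The tested gap between breeders and virgins, strain not excluded, differed by sex for 12 genes. Values are the difference in log2 fold change, then the male and female gap. The genes were Slc7a12 (-2.73, -3.06 and -0.33), Kynu (-1.48, -0.99 and 0.49), Id3 (-1.32, -1.78 and -0.46), Gsta2 (-1.30, -0.76 and 0.54) and Smad7 (-0.99, -0.47 and 0.52). Cpn1 (-0.97, -1.04 and -0.07), Spns2 (-0.93, -0.76 and 0.17) and Ecm1 (-0.85, -1.35 and -0.50) followed. The difference was positive for Irf6 (0.60, 0.38 and -0.21), Slc1a1 (0.65, 0.20 and -0.46), Erbb3 (0.78, 0.45 and -0.33) and Slc41a2 (1.06, 0.89 and -0.17).

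Libraries that entered no comparison held panel genes above the highest control library, by their lowest CPM. In the 2 Ar-deleted males of the paired-end run these were Prlr (158, controls of the Esr1 cross at most 22.5), Slc7a12 (145, at most 3.69), Cyp4a14 (296, at most 63) and Abcc3 (13.5, at most 2.47). In the 2 castrated males without injection these were Prlr (570, intact males of 8 weeks and another strain at most 57.6), Slc7a12 (200, at most 16.3), Cyp4a14 (374, at most 214), Abcc3 (37.1, at most 5.77) and Esr1 (34.2, at most 25.6). In the 2 ovariectomized females without injection these were Esr1 (28, intact females of 8 weeks at most 16.9), Slc7a13 (12.5, at most 11.8), Cyp4a14 (322, at most 310) and Cyp2e1 (592).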

How the results depend on the processing

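The fits without doubted libraries, without mitochondrial and ribosomal RNA genes and on halved counts were tests chosen only after the results were seen. Of 1450 called results of named genes none reversed. The call was lost for 9 of 1445 with DESeq2, 15 of 1450 with RLE size factors, 128 of 1450 without a low-count filter, 9 of 1449 without mitochondrial and ribosomal RNA genes and 61 of 501 with age as a covariate. It was lost for 27 of 142 in a single fit of the 12 intact groups, 38 of 387 without the doubted libraries, 0 of 252 with counts divided by 2, and 320 of 1450 when any library was left out. Of 243 called list results 198 lost the call with an estimated correlation, and 2 with RLE size factors. RLE size factors moved no count of calls by 1.5 times. The causes of the changes below were not tested. The Esr1 label compares libraries labelled with its deletion with their controls. Depth limits genes near 0 counts most in the single-end run, and the excess of even counts leaves the depth of the paired-end run uncertain.

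DESeq2 called 1 gene for sex at birth, 14 at 2 and 785 at 4 weeks, 156 for the breeding difference, 435 for ovariectomy, 7.7e+02 (rounded) and 175 for testosterone in castrated males and ovariectomized females, 90 for the difference of these, 62 for sex after gonadectomy and 405 for the smaller testosterone experiment. It called 64 for loss of Ar in females, 95, 97 and 41 for the Esr1 label in females, in males and in the paired-end run, and 8.9e+02 (rounded) between livers of deleted males and females. Without a low-count filter the counts were 8.9e+02 (rounded) for sex at 4 weeks, 31 for the breeding difference, 721 for the smaller testosterone experiment, and 2, 42 and 1 for the Esr1 label in females, in males and in the paired-end run. A single fit of the 12 intact groups called 1991 for sex at birth and 15 at 2 weeks. Without female 3a 5 genes were called at birth and without 3a and 3b 9, and without female breeder 2 the breeding difference held 7. With age as a covariate the Esr1 label called 1 in females and 37 in males, and the livers 414 for the loss in hepatocytes and 515 between deleted males and females.

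For the genes with a sex difference at 8 weeks the median log2 fold change is given where a call changed. With an estimated correlation the female-biased genes lost the call with ovariectomy (-0.31), testosterone in ovariectomized females (-0.07), the smaller testosterone experiment (-0.15) and the Esr1 label in females (-0.11), in males (0.18) and in the paired-end run (0.15), and for the testosterone effect by sex (-0.32). The male-biased genes lost it for the testosterone effect by sex (0.27), sex after gonadectomy (0.13) and the Esr1 label in the paired-end run (-0.12). With RLE size factors it was lost for female-biased genes with testosterone in ovariectomized females (-0.08). Without a fold minimum for the sets it was lost for male-biased genes and the testosterone effect by sex (0.06) and for female-biased genes with the Esr1 label in females (-0.04) and in the paired-end run (0.06). Male-biased genes gained a call there with loss of Ar in females (0.05), and the medians between the Tbx10 and Neurog2 lines moved to 0.01 for male-biased and 0.03 for female-biased genes. With the sets of the 9-week animals the call was lost for female-biased genes with the Esr1 label in females (-0.04), in males (0.07) and in the paired-end run (0.09), and the median for male-biased genes between the lines moved to -0.00.

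With each library left out in turn, counts ranged from 0 to 5 for sex at birth, 300 to 724 at 4 weeks, 6 to 68 for the breeding difference, 1641 to 2705 for castration, 41 to 190 for ovariectomy and 178 to 354 and 20 to 91 for testosterone in castrated males and ovariectomized females. They ranged from 0 to 12 for the testosterone effect by sex, 5 to 12 for sex after gonadectomy, 21 to 744 for the smaller testosterone experiment, 1 to 31 for loss of Ar in females, and 0 to 7 and 9 to 34 for the Esr1 label in females and males. They ranged from 2089 to 3211 for sex in the Neurog2 line, 907 to 1366 for the loss in hepatocytes and 62 to 423 between livers of deleted males and females.

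With the replicate number as a block, 0 genes were called for sex at birth, 5 at 2 weeks, 588 at 4 weeks, 2257 at 8 weeks and 3836 among breeders of 79 weeks, and 19 of 233 called gene results lost the call. Deviations of male and female libraries with the same number correlated from -0.27 to 0.33. Some libraries correlated best with their own number and others did not, which cannot decide whether the numbers pair the libraries.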

Other observations

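The overlaps here are tests chosen only after the results were seen. Males with loss of Ar in the nephron were also sequenced in the paired-end run (n = 2), where Ar stood at 3.75 and 4.44 CPM against 37.5 to 46.3 in control males of the Esr1 cross. They held Kap at 1378 and 1442 CPM (6950 to 11373 in the controls), Slc7a13 at 19 and 46.3 (784 to 1352), Cyp4b1 at 607 and 797 (5118 to 8121) and Slco1a1 at 1.13 and 11.3 (233 to 435). Castrated males without injection (n = 2) in the single-end run held Kap at 763 and 1081 CPM (8517 to 14388 in intact males of 8 weeks, another strain) and Slc7a13 at 19.4 and 40.5 (2044 to 2398). Ovariectomized females without injection (n = 2) held Kap at 1010 and 1539 (2667 to 5420 in intact females of 8 weeks, another strain), Slc7a12 at 173 and 222 (330 to 513) and Cyp4a14 at 322 and 391 (245 to 310). These differences were not tested.

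The genes changed by loss of Ar in all tissues overlapped with those of castration: 763 rose in both (247 expected if independent) and 1149 fell in both (284 expected), while 7 and 8 went opposite ways. Of the genes higher in males at 8 weeks, 1.1e+03 (rounded) were also higher in males of the Tbx10 line (223 expected) and 8.9e+02 (rounded) in those of the Neurog2 line (171 expected). Of the genes lower in males at 8 weeks, 776 were also lower in males of the Tbx10 line (199 expected) and 505 in those of the Neurog2 line (132 expected). Of liver genes that rose with hepatocyte loss of Ar, 28 were lower in deleted males than in females (6.7 expected) and 2 higher (7.06). Of those that fell 24 were higher (8.66 expected) and 4 lower (8.22). The second comparison mixes sex with loss.

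Nuclear receptors and cofactors were called by camera in 3 of 30 comparisons, with the lowest adjusted p = 0.0256 for testosterone in castrated males (adjusted p = 0.296 with an estimated correlation). Of these genes 7 rose in males among breeders, and 10 fell with loss of Ar in all tissues. Adrenal cortex markers were called in 2 of 26, with the lowest adjusted p = 0.0265 for loss of Ar in females (adjusted p = 0.32 with an estimated correlation), and exocrine pancreas markers in none, with the lowest adjusted p = 0.0793. In liver bile acid metabolism (lowest adjusted p = 0.074), acute phase proteins (0.0529) and non-parenchymal markers (0.0544) were called in none of the 4 comparisons, with 5, 3 and 0 members higher and 3, 2 and 3 lower in control males than in females across runs.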
